A study of Caenorhabditis elegans with 6 samples.

How the data were processed

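Poly(A)-selected RNA from whole wild-type Caenorhabditis elegans labelled as the L4 larval stage was sequenced, with 3 libraries from worms on ordinary plates of Escherichia coli OP50 and 3 from worms on plates with 50 µM 5-fluoro-2′-deoxyuridine (FUDR), a nucleoside analogue whose monophosphate inhibits thymidylate synthase. Per the labels' protocols, RNA was purified on Zymo Direct-zol columns, and libraries were made with NEBNext poly(A) selection and the NEBNext Ultra RNA kit. The deposited table holds raw counts of reads per gene, and the submitters' processing notes name STAR, HTSeq and the genome build WBcel235. Versions, the annotation release and the strand setting of the counting are not given in the sources used here. Reads from genes that overlap on opposite strands therefore may not be told apart, and genes with near-identical copies lose reads that align to several places.

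The table has 46926 genes and 5 HTSeq summary rows. The summary rows were kept out of library sizes and tests and held between 4.55% and 5.33% of all rows' counts per library. Counts not assigned to any gene made up between 0.314% and 0.465%, and reads that did not align uniquely made up between 2.70% and 3.50%. All 46926 gene identifiers were found in the Ensembl release 115 annotation of WBcel235, which supplied positions and biotypes. A name was found for 44115, and the other 2811 are given by identifier. Library totals over genes ran from 61312034 to 99234226 counts, a ratio of 1.62. A floor of 3 counts corresponds to between 0.0302 and 0.0489 CPM (counts scaled to a common library size), and such floors and count intervals cover counting error only.

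Groups were taken from the sample labels. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be in part technical. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 19.6, and all 6 were used as separate samples.

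Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr by group (minimum count 10, minimum total count 15), TMM normalization and the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are TMM-normalized. Fold changes are FUDR over OP50 unless stated. Gene lists and families of gene symbols were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, again with Benjamini-Hochberg adjustment. Lists needed 3 tested members and families 10. The test was repeated with a correlation estimated per list and with fry. With an estimated correlation, camera takes its degrees of freedom from the few libraries and not from the genes, which makes it stricter. Calls on the X chromosome were compared with those on autosomes by a two-sided Fisher's exact test, and the mitochondrial share by a two-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1.

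The design, the alternatives, the 46 gene lists and the rule for named genes were fixed before the data were examined. The mitochondrially encoded list was later matched by chromosome and biotype, since its symbols were absent from the name table. Of 894 symbols written out in lists, 873 (97.7%) were found, and 32 lists share a gene with another. The text names 8 genes whatever their values (tyms-1, rnr-1, egl-1, ced-13, cep-1, rad-51, col-19 and vit-2). It also names the 6 genes up and the 6 down with the largest log2 fold change among called genes with a mean of at least 5 CPM, no overlap between the groups' libraries and a symbol other than a clone name. For each list it names up to 4 members with the smallest p, and for each family 2. Members named to account for a count of 5 or fewer, and genes singled out in the closing section, were chosen after their values were seen.

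The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors (RLE, upper quartile, none), no filter, a filter of 5 CPM in 3 libraries, the non-robust fit, the replicate number as a block, a test against a 1.5-fold change and leaving out each library. Thinning to the shallowest library and a fit of protein-coding genes alone were added after the data were seen. The gene test was tested on simulated data for FUDR against OP50 with 16845 genes. It recovered 70 of 98 genes changed 2-fold (71.4%) and 38 of 99 changed 1.5-fold (38.4%), and 13 of its calls, 10.7%, were false, above the nominal rate. With no change simulated, 2 genes and 0 of 50 lists were called. That simulation drew genes independently and does not show how camera behaves when genes vary together. The simulation with changes altered few genes, drawn evenly as rises and falls, while 41% of tested genes were called in the real comparison. Its rates of recovery and of false calls therefore need not hold for these data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.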

Results

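The series asked how gene expression in wild-type worms labelled as L4 larvae differs between plates with 50 µM FUDR and ordinary OP50 plates. Each group had 3 libraries of whole worms. The OP50 libraries held 99234226, 66005990 and 80981975 gene counts and the FUDR libraries 61312034, 84750980 and 78769746. Log2 CPM correlated between 0.985 and 0.992 within groups and between 0.958 and 0.97 across them. The first principal component, with 69.14% of the variance, parted the groups.

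In FUDR, 31 of 33 tested DNA replication genes, 45 of 50 cell cycle genes and 34 of 38 oocyte genes were lower. Of 128 neuropeptide genes 76 were higher, as were 27 of 40 antimicrobial peptide genes and 19 of 46 glutathione S-transferase genes. These lists passed camera with a preset correlation between genes. With an estimated correlation, which also leaves the test few degrees of freedom, 0 of the 46 lists passed. The P-glycoprotein transporter gene pgp-8 rose 88.1-fold and the glutathione S-transferase gene gst-24 rose 60.8-fold, while the cytochrome P450 gene cyp-35D1 was 31.3-fold lower. Of 17022 genes tested, 3397 rose and 3582 fell at an edgeR adjusted p under 0.05. At least a 2-fold change was seen in 1348 of the genes that rose and in 310 of those that fell. Genes under 1 CPM gave 669 rises and 80 falls, and genes over 100 CPM gave 175 rises and 970 falls. The libraries of the groups did not overlap for 54.74% of tested genes, against 10% by chance. The share of calls that rose was 48.67% with TMM, 66.63% with upper quartile scaling and 75.07% with library size only, which moved the median log2 fold change of all genes by 0.23. Directions below are relative to TMM scaling, and counts in lists and families were not compared with genes of like expression level.

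**Figure D1:**
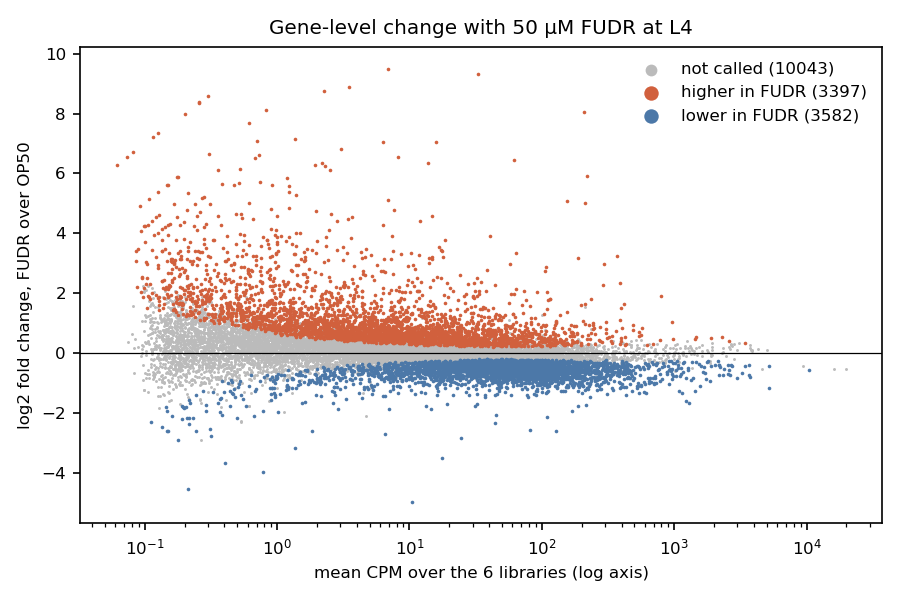
Log2 fold change of FUDR over OP50 against the mean CPM of each tested gene over the 6 libraries, on a log axis. The 3397 genes called higher are orange, the 3582 called lower are blue, and the others are grey. Large rises lie mostly at low CPM and falls mostly at high CPM.

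The genes of thymidylate synthase, which FUDR targets, and of ribonucleotide reductase were lower. The thymidylate synthase gene tyms-1 (chromosome I, 5138250 to 5139382, WBcel235) went from 22.1 ± 3.93 to 11.9 ± 0.837 CPM (SD over 3 libraries), a log2 fold change of −0.89 ± 0.139 (SE, edgeR adjusted p = 0.00141). The ribonucleotide reductase gene rnr-1 (chromosome III, 9225339 to 9228798) went from 310 ± 8.89 to 143 ± 19.3 CPM, a log2 fold change of −1.12 ± 0.112 (edgeR adjusted p = 0.00023). In the pyrimidine and nucleotide metabolism list, 9 of 17 tested members fell, including the dUTPase gene dut-1 (−0.75), the dihydropyrimidine dehydrogenase gene dpyd-1 (−0.74) and the UMP synthase gene umps-1 (−0.68). The exceptions upb-1 (0.60) and cdd-2 (0.43) rose. The counts were 3 up and 9 down adjusted over the list alone, and 5 up and 9 down with library size only. In the camera test the adjusted p of 0.0173 became an adjusted p = 0.347 with an estimated correlation, and the call also ended with the 5 CPM filter (adjusted p = 0.115). No member was called higher without OP50 replicate 2 (adjusted p = 0.0584 for upb-1 and 0.078 for cdd-2) or without FUDR replicate 3 (0.0591 and 0.123). Nor was cdd-2 called without OP50 replicate 1 (0.112) or FUDR replicate 2 (0.0953). The tyms-1 gene overlaps Y110A7A.24 and rnr-1 overlaps T23G5.7.

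The p53 homologue gene cep-1 (chromosome I, 8324286 to 8328859) fell from 48.5 ± 1.88 to 33.7 ± 0.872 CPM, a log2 fold change of −0.52 ± 0.0745 (edgeR adjusted p = 0.000913). The recombinase gene rad-51 (chromosome IV, 10281634 to 10284244) fell by less, at −0.28 ± 0.0756 (edgeR adjusted p = 0.0173). It was not called without a scaling factor (−0.05, adjusted p = 0.639), with upper quartile scaling (−0.13, adjusted p = 0.165), with the 5 CPM filter (adjusted p = 0.0608), or without OP50 replicate 1 (adjusted p = 0.0541) or 3 (adjusted p = 0.0616). The pro-apoptotic BH3-only gene egl-1 (chromosome V, 14431308 to 14432359) rose from 0.341 ± 0.146 to 0.728 ± 0.161 CPM, a log2 fold change of 1.08 ± 0.38 (edgeR adjusted p = 0.0489). That call was lost with RLE scaling (adjusted p = 0.0512), with the non-robust fit (0.0501) and without OP50 replicate 2 (0.107) or 3 (0.127) or FUDR replicate 1 (0.065), 2 (0.171) or 3 (0.0513). The BH3-only gene ced-13 was not tested, with counts of 0, 0 and 2 in the OP50 libraries and 4, 2 and 3 in the FUDR libraries. In the apoptosis list 7 of 21 tested members fell, including the germline regulator gla-3 (−1.25), ced-9 (−0.68) and ced-5 (−0.83). In that list cps-6 (0.27) and egl-1 rose, with the same 2 up and 7 down adjusted over the list alone. Its camera adjusted p was 0.00849, against an adjusted p = 0.488 with an estimated correlation and 0.115 with the 5 CPM filter, and its median of −0.17 became 0.06 with library size only. No member was called higher without OP50 replicate 2 or 3 or FUDR replicate 2 or 3, where cps-6 had an adjusted p between 0.0623 and 0.187.

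Among called genes with a mean of at least 5 CPM, separate libraries and a symbol other than a clone name, the 6 largest rises were in the claudin-like genes clc-32 and clc-11, the F-box gene fbxa-163, pgp-8, gst-24 and the poly(ADP-ribose) glycohydrolase gene parg-2. The clc-32 gene (chromosome V, 16140313 to 16141171) had 4 counts over the OP50 libraries, all in 1 library, and 3502 over the FUDR libraries, a ratio of 818 after TMM scaling (95% interval 319 to 3000, counting error only). The neighbouring clc-11 (chromosome V, 16138760 to 16139629) rose 92.8-fold, fbxa-163 (chromosome II, 1609252 to 1610730) rose 645-fold and parg-2 (chromosome IV, 8712408 to 8715132) rose 34.4-fold. The pgp-8 level (chromosome X, 10859301 to 10864422) went from a range of 0.9 to 1.79 CPM to a range of 100.41 to 151.56 CPM and gst-24 (chromosome II, 13610443 to 13611366) from 7.05 ± 2.46 to 432 ± 162 CPM. All 6 had an edgeR adjusted p of at most 0.00016.

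Under the same limits, the 6 largest falls began with cyp-35D1 (chromosome V, 16069238 to 16071318), from 20.3 ± 7.87 to 0.655 ± 0.0962 CPM, and cyp-35A5 (chromosome V, 3936326 to 3938597), 11.4-fold lower. The gene rips-1 (chromosome V, 3772021 to 3774609) was 7.16-fold lower and the UDP-glucuronosyltransferase gene ugt-53 (chromosome V, 2849343 to 2852028) 6.59-fold lower. The folate transporter family gene folt-2 (chromosome V, 2872465 to 2875600) was 6.07-fold lower and the cysteine synthase-like gene cysl-2 (chromosome II, 14492874 to 14494451) 6.01-fold lower. The OP50 libraries themselves spread widely for folt-2, at 69.98, 243.74 and 350.53 CPM, and for cysl-2, at 209.1, 145.99 and 63.47 CPM. The folt-2 call was lost without the count filter (adjusted p = 0.0607) and without FUDR replicate 1 (0.0913) or 3 (0.1), and the cysl-2 call without FUDR replicate 3 (0.0574). The rips-1 gene overlaps cysl-3 and cysl-2 overlaps vnut-1.

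**Figure D2:**
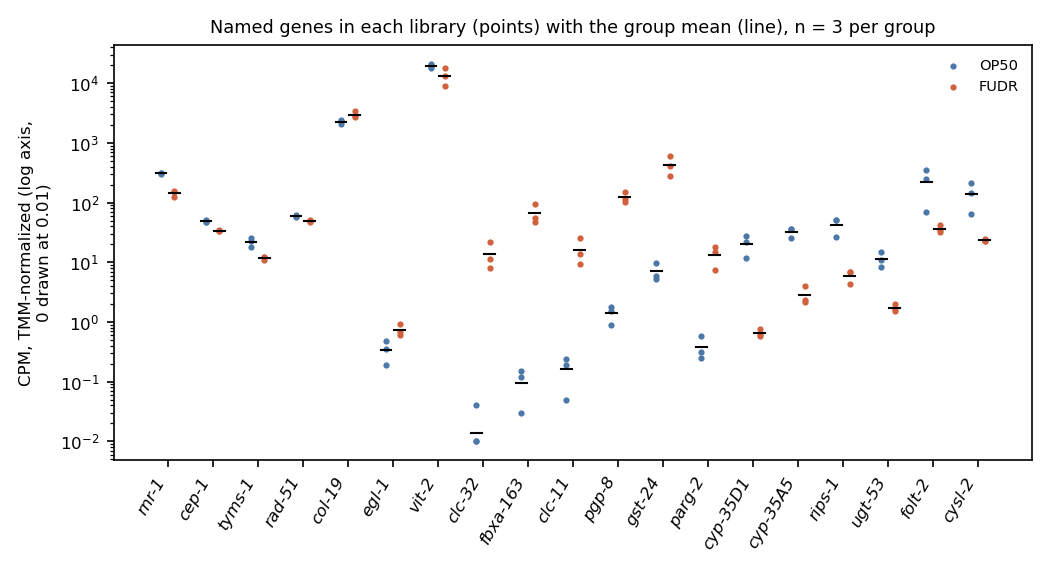
CPM of the 19 tested genes named by the fixed part and the largest-change part of the rule, on a log axis, with a point per library, a line at each group's mean and values of 0 drawn at 0.01. The FUDR libraries of pgp-8 lie between 100.41 and 151.56 CPM and its OP50 libraries between 0.9 and 1.79 CPM.

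Most genes of the DNA replication, cell cycle, germ granule, oogenesis, meiosis and DNA repair lists fell. Of 33 tested DNA replication genes 31 fell and 0 rose, led by the replicative helicase genes mcm-7 (−1.24 ± 0.109), mcm-5 (−0.87), mcm-6 (−0.88) and mcm-3 (−1.13). Of 50 cell cycle and mitosis genes 45 fell and 0 rose, including the polo-like kinase gene plk-1 (−1.03), cyb-2.1 (−0.77), cdc-25.1 (−0.93) and zyg-1 (−0.70). Of 50 germ granule and germline RNA genes 41 fell and 0 rose, with the nuclear Argonaute gene hrde-1 at −1.40, the RNA helicase gene cgh-1 at −1.61, wago-1 at −1.11 and ego-1 at −1.0. Of 38 oogenesis genes 34 fell, including inx-22 (−1.0), the yolk receptor gene rme-2 (−1.28), egg-3 (−1.06) and egg-5 (−1.06), and only fbxa-158 (4.66), which is also in the intracellular pathogen response list, rose. Of 39 meiosis genes 28 fell, among them xnd-1 (−1.25), sun-1 (−0.78), coh-4 (−0.83) and lin-5 (−0.76), and only syp-1 (0.35) rose, a call lost without OP50 replicate 3 (0.30, adjusted p = 0.0578). Of 47 DNA repair and checkpoint genes 36 fell and 0 rose, with polh-1 at −0.81, pms-2 at −0.86, clsp-1 at −0.73 and chk-1 at −0.76. The numbers of falls adjusted over the list alone were 31, 47, 43, 34, 29 and 38 in the same order, with 2 rises among repair genes and 1 each in the oogenesis and meiosis lists. Tested with camera, the adjusted p was 6.68e-12, 1.14e-15, 9.35e-15, 9.35e-15, 4.42e-09 and 4.5e-10, and the adjusted p was 0.347 with an estimated correlation for each of the 6 lists. With library size only, 14 meiosis genes and 20 repair genes fell, and 4 repair genes rose (3 with upper quartile scaling).

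Sperm genes did not move with oocyte genes. Of 51 tested spermatogenesis genes 9 rose and 4 fell (9 and 3 adjusted over the list alone). As a set it did not pass camera (adjusted p = 0.428, median log2 fold change 0.10). The genes with the smallest p were zipt-7.1 (−0.52), spe-39 (−0.54) and spe-44 (−0.54), which fell with fer-1 (−0.67). The fer-1 call was lost without OP50 replicate 1 (adjusted p = 0.104) or 2 (0.0572) or FUDR replicate 2 (0.0827), 7 members fell without FUDR replicate 1, and 22 rose with library size only. Of 31 major sperm protein genes 6 rose and 0 fell (4 and 0 adjusted over the list alone), including msp-64 (0.32), msp-50 (0.32), msp-40 (0.34) and msp-63 (0.57), with a camera adjusted p of 0.0271 and an adjusted p = 0.601 with an estimated correlation. That count was 1 without OP50 replicate 3, 3 without OP50 replicate 1 or 2 or FUDR replicate 2, and 25 with library size only. This set did not pass without OP50 replicate 2 (adjusted p = 0.0684) or 3 (0.156) or FUDR replicate 1 (0.0726). Of 9 tested genes of the sperm-enriched nspd family 8 rose (9 adjusted over the list alone), with nspd-10 at 0.61, nspd-2 at 0.61, nspd-1 at 0.51 and nspd-6 at 0.41, a camera adjusted p of 0.0103 and an adjusted p = 0.549 with an estimated correlation. That count was 2 without OP50 replicate 1 or 3 and 4 without OP50 replicate 2 or FUDR replicate 2, and fry gave the list an adjusted p of 0.0561. Members of both families are near-identical in sequence, so counts of single members are uncertain. Of 13 male-enriched markers try-5 (3.47), tbb-6 (1.62), klp-6 (1.54) and clec-207 (2.02) rose and 0 fell, also adjusted over the list alone, with a camera adjusted p of 0.0242 and an adjusted p = 0.347 with an estimated correlation. The clec-207 call was lost without OP50 replicate 1 (adjusted p = 0.0665) or 3 (0.0663) or FUDR replicate 2 (0.0894), and the list's call with library size only (0.0564).

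Yolk, timing and cuticle genes were mixed. The yolk protein gene vit-2 (chromosome X, 5101042 to 5106169) had 19200 ± 1420 CPM in OP50 and 13200 ± 4370 CPM in FUDR and was not called (−0.54 ± 0.218, edgeR adjusted p = 0.0776), though it was called by DESeq2 (adjusted p = 0.0214) and without FUDR replicate 1 (0.00397). Of 6 vitellogenin genes vit-1 (−1.16), vit-3 (−0.81) and vit-4 (−0.74) fell and 0 rose, also adjusted over the list alone, with a camera adjusted p of 0.0271 and an adjusted p = 0.549 with an estimated correlation. The number that fell was 6 without FUDR replicate 1 and 1 without OP50 replicate 2 or 3 or FUDR replicate 2 or 3. It was also 1 with library size only, where vit-3 (adjusted p = 0.056) and vit-4 (0.0573) were not called. The list did not pass with fry (0.0882), without FUDR replicate 3 (0.0786) or with the 5 CPM filter (0.0655). The adult cuticle collagen gene col-19 (chromosome X, 421707 to 422691) rose from 2240 ± 154 to 2970 ± 365 CPM (0.41 ± 0.12, edgeR adjusted p = 0.0246), a call lost without OP50 replicate 1 (0.0789), 2 (0.06) or 3 (0.0716). Of 149 tested cuticle collagens 32 rose and 11 fell (30 and 7 adjusted over the list alone), with col-45 (2.11) and col-65 (0.64) higher and rol-8 (−0.66) and sqt-3 (−0.75) lower. By camera the adjusted p of 0.0473 was an adjusted p = 0.697 with an estimated correlation, 0.301 without OP50 replicate 1, 0.0526 without FUDR replicate 1 and 0.136 without FUDR replicate 3. It was 0.0569 with library size only, 0.0506 with RLE scaling and 0.123 with fry. The number of collagens that fell was 7 without OP50 replicate 2 and 5 without FUDR replicate 2, and with library size only 73 rose and 4 fell.

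Among 34 molting genes 15 fell (16 adjusted over the list alone), including cut-2 (−1.01), rol-3 (−0.66) and grl-7 (−0.76), and mlt-7 (0.48) rose, with a camera adjusted p of 0.00599 and an adjusted p = 0.347 with an estimated correlation. The number that fell was 7 with library size only. As a set it did not pass with the 5 CPM filter (adjusted p = 0.055). Among 20 developmental timing genes 6 fell, including lin-41 (−1.48), nhr-23 (−0.73), myrf-1 (−0.82) and lin-42 (−1.05), and lin-46 (0.64) and pan-1 (0.28) rose, with the same counts adjusted over the list alone. The camera adjusted p was 0.03 and the adjusted p was 0.505 with an estimated correlation. The median of −0.21 was 0.01 with library size only, and neither rise was called without OP50 replicate 1, 2 or 3 or FUDR replicate 2 or 3 (adjusted p between 0.0527 and 0.149). The timing call was lost with fry (0.0504), with the 5 CPM filter (0.121) and without OP50 replicate 1 (0.0638) or FUDR replicate 3 (0.0608). Of 46 groundhog, warthog and other hedgehog-related genes 8 fell, including wrt-4 (−1.41), wrt-9 (−1.11), grd-1 (−0.85) and grl-7, and grd-10 (0.78), grd-5 (0.72) and grd-13 (0.57) rose (the same adjusted over the list alone). This set did not pass camera (adjusted p = 0.426), whose direction was down while the median was 0.06, and 5 members rose without OP50 replicate 3. In this list 7 rose and 5 fell with library size only. The grd-13 gene was not called without OP50 replicate 1 (adjusted p = 0.0701) or 2 (0.0815) or FUDR replicate 2 (0.0575) or 3 (0.06).

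Detoxification genes changed in both directions. Of 46 tested glutathione S-transferase genes 19 rose, including gst-24 (5.93), gst-30 (1.95), gst-38 (5.08) and gst-15 (1.41), while gst-19 (−3.96) and gst-27 (−0.45) fell, with the same counts adjusted over the list alone. Tested with camera, the adjusted p was 0.000623 and the adjusted p was 0.434 with an estimated correlation, and 4 members fell without OP50 replicate 1 and 1 without FUDR replicate 2, where gst-27 was not called (adjusted p = 0.0535). Of 70 cytochrome P450 genes 24 rose and 13 fell (the same adjusted over the list alone), with cyp-29A4 at 3.50 and cyp-35D1, cyp-35A5 and cyp-35C1 at −4.97, −3.51 and −2.32. The number that rose was 15 without FUDR replicate 2. The list did not pass camera (adjusted p = 0.244). Of 66 UDP-glucuronosyltransferase genes 24 rose and 15 fell (26 and 16 adjusted over the list alone), with ugt-39 at 3.21 and ugt-53, ugt-22 and ugt-5 at −2.72, −1.95 and −1.38. As a set it did not pass camera (adjusted p = 0.426), and with library size only 29 rose and 11 fell. Of 22 ABC transporter genes 8 rose, including pgp-8 (6.46), pgp-9 (0.94) and pgp-4 (1.03), and mrp-4 (−1.14), mrp-7 (−0.74) and pgp-12 (−0.60) fell (9 and 3 adjusted over the list alone), with a camera adjusted p of 0.211. ABC transporter genes rose in 13 cases with library size only, and pgp-12 was not called there (adjusted p = 0.0695). In the oxidative stress and SKN-1 target list 10 of 36 genes rose, including gst-30, gst-38, gst-14 (2.67) and sod-4 (0.66), and skn-1 (−0.57), nit-1 (−0.56), gss-1 (−0.27), dhs-8 (−1.39) and sod-1 (−0.23) fell (10 and 6 adjusted over the list alone), with a camera adjusted p of 0.141. The rises were 21 with library size only, 5 without OP50 replicate 3 and 6 without OP50 replicate 1 or FUDR replicate 2, and the falls were 1 with library size only and 2 without OP50 replicate 1 or 2 or FUDR replicate 2, so that nit-1, gss-1, dhs-8 and sod-1 each depend on single libraries (adjusted p up to 0.0844, 0.106, 0.119 and 0.136). That list passed camera with the 5 CPM filter (0.0156). Of 30 targets of the insulin pathway factor DAF-16, 13 rose, including dod-22 (2.62), fat-5 (2.75), dod-21 (3.75) and dod-3 (4.43), and lea-1 (−1.14) and daf-28 (−0.35) fell (14 and 2 adjusted over the list alone). By camera the adjusted p was 0.00264 and the adjusted p was 0.3 with an estimated correlation, and 0 members fell with library size only or without FUDR replicate 2 or 3 (adjusted p = 0.0978 and 0.28 for lea-1, 0.162 and 0.0739 for daf-28).

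Innate immune lists held more rises than falls. Among all tested genes of 1 to 5 CPM 923 of 3403 rose and 172 fell, and of 5 to 20 CPM 1011 of 3843 rose and 527 fell. The C-type lectin counts lie near these shares. Of 31 pathogen response genes 21 rose and 2 fell (21 and 3 adjusted over the list alone), including mul-1 (3.33 ± 0.159), dod-22, C17H12.8 (3.17) and irg-2 (2.93), and the genes that fell were atf-7 (−0.29) and hpo-15 (−0.29). Of 40 antimicrobial peptide genes 27 rose (27 adjusted over the list alone), including fipr-29 (1.70), fipr-24 (5.01), fipr-22 (3.72) and nlp-31 (1.30), and cnc-7 (−2.16) fell. Of 35 lysozyme and saposin-like genes 15 rose and 0 fell (the same adjusted over the list alone), with lys-1 going from 335 to 1260 CPM (1.91), lys-2 from 67.6 to 525 CPM (2.96), lys-4 from 25.4 to 98.7 CPM (1.96) and lys-3 at 3.89. Of 32 intracellular pathogen response genes 16 rose (17 adjusted over the list alone), including skr-4 (1.14), pals-23 (1.15), pals-24 (1.39) and pals-6 (3.63), and the RNA helicase gene drh-1 (−0.64) fell. Of 150 C-type lectin genes 38 rose and 14 fell (the same adjusted over the list alone), including clec-47 (4.12), clec-52 (2.97), clec-143 (2.34) and clec-5 (1.31). In the camera test the adjusted p was 6.82e-06, 2.79e-06, 0.000414, 0.000356 and 0.019 in the same order, and the adjusted p was 0.3, 0.347, 0.336, 0.3 and 0.3 with an estimated correlation. The falls of atf-7, hpo-15 and cnc-7 were not called with library size only (adjusted p = 0.546, 0.658 and 0.0502), nor without OP50 replicate 1 (0.064, 0.0696 and 0.121) or 2 (0.0697, 0.0847 and 0.11) or FUDR replicate 2 (0.0606, 0.1 and 0.0934). The C-type lectin list did not pass with library size only (0.084), where 61 rose and 9 fell.

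Genes of the responses to misfolded proteins changed in both directions. Of 23 genes of the endoplasmic reticulum unfolded protein response 12 fell and 0 rose (the same adjusted over the list alone), including hsp-110 (−0.83), the BiP gene hsp-4 (−0.60), sel-11 (−0.71) and tram-1 (−0.65). The camera adjusted p was 0.000204 and the adjusted p was 0.488 with an estimated correlation, and 7 members fell with library size only. Among all tested genes over 100 CPM 970 of 1931 fell, a share near the 12 of 23 of this list. In the mitochondrial unfolded protein response list 7 of 18 genes fell, including the chaperone genes hsp-60 (−1.32) and hsp-6 (−1.03) and the transcription factor gene atfs-1 (−0.69). The immune genes lys-2 (2.96) and clec-4 (2.07) rose with ubl-5 (0.95) and clpp-1 (0.37), with the same counts adjusted over the list alone. This set did not pass camera (adjusted p = 0.426), with clpp-1 not called without OP50 replicate 2 (0.0645) or FUDR replicate 2 (0.0601). In the heat shock list hsp-17 (1.90) and hsp-16.2 (3.12) were among 6 of 24 genes that rose, and dnj-13 (−0.80) and hsp-110 among 9 that fell (8 and 9 adjusted over the list alone), with a camera adjusted p of 0.545. Both of these lists had a negative median (−0.10 and −0.07), a camera direction of down and a positive mean (0.15 and 0.42), and their medians were 0.13 and 0.16 with library size only, where 6 rose and 5 fell in the first and 9 rose and 7 fell in the second.

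Metabolic and translation genes fell in part. Among all tested genes over 100 CPM 970 of 1931 fell and 175 rose. Among those of 20 to 100 CPM 1833 of 4582 fell and 619 rose. The falls in the ribosomal protein list and in the methionine, folate and propionate list lie near these shares. Of 33 genes of the list of methionine, folate and propionate metabolism 17 fell (21 adjusted over the list alone), including the nuclear receptor gene nhr-114 (−2.06 ± 0.117), the S-adenosylmethionine synthetase gene sams-3 (−1.08), ahcy-1 (−1.11) and gldc-1 (−0.98), and cblc-1 (0.41) and nhr-10 (0.30) rose. By camera the adjusted p was 3.6e-05 and the adjusted p was 0.347 with an estimated correlation, 4 members rose and 11 fell with library size only, and nhr-10 was not called without OP50 replicate 1 (0.0774), 2 (0.0656) or 3 (0.0708) or FUDR replicate 2 (0.0727). In lipid metabolism 12 of 51 genes rose, including fat-5 (2.75) and lbp-5 (1.44), and 16 fell, including cpt-4 (−1.71) and elo-3 (−0.87) (14 and 17 adjusted over the list alone), with a camera adjusted p of 0.397 and a median of −0.13 that was 0.11 with library size only (16 up and 13 down). Of 81 cytosolic ribosomal protein genes 37 fell (39 adjusted over the list alone), including rpl-7A (−1.25), rpl-20 (−0.78), rpl-12 (−0.76) and rpl-1 (−0.83), and rpl-24.2 (0.64), rpl-11.2 (0.45) and rpl-42 (0.47) rose. In the camera test the adjusted p was 5.26e-05 and the adjusted p was 0.488 with an estimated correlation. The number that fell was 18 without OP50 replicate 2, 19 without OP50 replicate 3 and 15 without FUDR replicate 2, and with library size only 15 rose, 11 fell and the median of −0.21 became 0.03. The number that rose was 1 without OP50 replicate 2 or 3 or FUDR replicate 2, and 2 without OP50 replicate 1 or FUDR replicate 3. Of 37 ribosome biogenesis genes 10 fell, including nol-56 (−0.76), fib-1 (−0.71), exos-2 (−0.58) and nol-6 (−0.66), and 6 rose (the same adjusted over the list alone), with a camera adjusted p of 0.303, 1 rise without OP50 replicate 1, 3 without OP50 replicate 2 and a median of −0.03 that was 0.20 with library size only (15 up and 7 down).

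Nuclear genes of oxidative phosphorylation and mitochondrially encoded genes were set side by side. The share of the nuclear genes that fell was under that of all tested genes over 100 CPM (970 of 1931). Of 50 nuclear genes 14 fell (13 adjusted over the list alone), including the ATP synthase genes atp-2 (−0.69) and atp-1 (−0.73), sdha-1 (−0.58) and cox-7C (−0.35), and nduf-5 (0.33) rose, with a camera adjusted p of 0.0194 and an adjusted p = 0.601 with an estimated correlation. The number that fell was 3 without OP50 replicate 3 and 4 without OP50 replicate 2 or FUDR replicate 2. It was 20 without FUDR replicate 1, where 3 rose. The nduf-5 gene was not called without OP50 replicate 1 (0.106), 2 (0.0611) or 3 (0.0873) or FUDR replicate 2 (0.0907), nor cox-7C without OP50 replicate 2 (0.0637) or 3 (0.0649) or FUDR replicate 2 (0.07). With library size only 14 rose, 3 fell and the median of −0.15 became 0.07. The list did not pass there (0.285), with fry (0.0767) or with the 5 CPM filter (0.492). Of 12 mitochondrially encoded protein genes ND1 (0.59) and WBGene00010965 (0.47) rose and 0 fell (1 and 0 adjusted over the list alone), with a camera adjusted p of 0.102, while WBGene00010963 (0.35, adjusted p = 0.0534) and WBGene00000829 (0.32, adjusted p = 0.0672) were not called. DESeq2 called them (0.042 and 0.0494), as did the fits with library size only (0.00482 and 0.00507), upper quartile scaling (0.0136 and 0.0159), the 5 CPM filter (0.0219 and 0.023) and without FUDR replicate 1 (0.0287 and 0.0396). WBGene00010963 was also called with limma-voom (0.0497), without the count filter (0.0348), after thinning (0.0494) and without OP50 replicate 3 (0.0465). The number that rose was 6 without FUDR replicate 1, 3 without OP50 replicate 3, 1 without OP50 replicate 1 or 2 or FUDR replicate 2, and 7 with library size only. That list passed without FUDR replicate 1 (0.0146) or OP50 replicate 3 (0.0484) and with the 5 CPM filter (0.0287). The share of counts in mitochondrially encoded protein and rRNA genes was 0.952% ± 0.0618 in OP50 and 1.30% ± 0.25 in FUDR (SD, n = 3 each), a difference of 0.351 percentage points (two-sided exact permutation p = 0.1, the smallest possible). The difference was 0.218 without FUDR replicate 3 and 0.465 without FUDR replicate 1.

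Histone genes rose in 15 of 47 cases (14 adjusted over the list alone), including his-35 (0.57), his-37 (0.66) and his-41 (0.54), and his-74 (−0.89) and his-24 (−0.50) fell. Tested with camera, the adjusted p was 0.00149, the adjusted p was 0.347 with an estimated correlation, and the call ended with the 5 CPM filter (adjusted p = 0.276). Replication-dependent histone mRNAs of animals mostly lack a poly(A) tail and were measured here after poly(A) selection, and many histone genes have near-identical copies.

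Neuropeptide genes and markers of single tissues were counted next. Of 128 tested neuropeptide genes 76 rose and 0 fell (85 and 1 adjusted over the list alone), including ins-7 (1.37), flp-32 (1.22), flp-18 (0.72) and flp-24 (0.86), with a camera adjusted p of 1.29e-12 and an adjusted p = 0.347 with an estimated correlation. Of 36 neuron markers 12 rose, including flp-18, sbt-1 (0.56) and pdf-1 (0.55), and the tyrosine decarboxylase gene tdc-1 (−0.90) and unc-18 (−0.29) fell (the same adjusted over the list alone), with a camera adjusted p of 0.00723 and an adjusted p = 0.347 with an estimated correlation. The neuron markers that rose numbered 7 without OP50 replicate 2 and 23 with library size only. The unc-18 gene was not called without OP50 replicate 2 (0.11) or 3 (0.108) or FUDR replicate 2 (0.105). Of 25 body wall muscle markers unc-98 (0.57) and pat-10 (0.48) rose and unc-45 (−0.30) fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.545), and 9 fell without FUDR replicate 1 and 0 without OP50 replicate 2 (adjusted p = 0.0732 for unc-45) or 3 (0.0739). The muscle markers that rose numbered 4 without FUDR replicate 3 and 3 without OP50 replicate 3. The median for muscle of −0.09 was 0.13 with library size only, where 8 rose and 0 fell (unc-45 −0.08, adjusted p = 0.456). The titin-related gene ttn-1 was not called (−1.04, adjusted p = 0.0504) but was with limma-voom (0.024), the non-robust fit (0.0407), protein-coding genes alone (0.049) and without FUDR replicate 1 (−1.60, adjusted p = 0.00171). Of 21 pharynx markers tnc-2 (0.69), phat-6 (0.57) and tni-4 (0.42) rose and 0 fell, and phat-1 had −0.60 (adjusted p = 0.149), with the same counts adjusted over the list alone and a camera adjusted p of 0.545. The tni-4 call was lost without OP50 replicate 2 (0.0566) or 3 (0.0543), phat-1 was called lower without FUDR replicate 1 (0.0423), and 5 rose with library size only.

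Of 27 intestine markers 8 rose, including pgp-1 (1.23) and far-3 (1.95), and pho-1 (−1.01), cpr-6 (−0.62), pept-1 (−0.50) and nhx-2 (−0.36) fell (the same adjusted over the list alone, camera adjusted p = 0.468), with 13 rises with library size only, 5 without OP50 replicate 1 or FUDR replicate 2 and nhx-2 not called without OP50 replicate 2 (0.0682) or 3 (0.135) or FUDR replicate 2 (0.0955) or 3 (0.0733). Of 22 hypodermis and seam markers grd-10, grd-13 (0.57) and nhr-73 (1.91) rose and fasn-1 (−0.77), lin-26 (−0.58), egl-18 (−0.45) and pcp-2 (−0.36) fell (the same adjusted over the list alone, camera adjusted p = 0.649), with a mean of 0.07 and a median of −0.04 that was 0.20 with library size only (5 up and 2 down). The rises numbered 1 without OP50 replicate 2 or FUDR replicate 2 or 3 and 2 without OP50 replicate 1 or 3. The pcp-2 gene was not called without OP50 replicate 2 (0.0936) or 3 (0.0774) or FUDR replicate 2 (0.12), nor egl-18 without OP50 replicate 2 (0.0547). Of 14 coelomocyte and excretory markers cup-4 (0.63) and sulp-4 (0.36) rose and exc-4 (−0.46) and vha-8 (−0.38) fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.787). The calls of sulp-4 (adjusted p up to 0.117) and vha-8 (up to 0.0812) were lost without OP50 replicate 2 or 3 or FUDR replicate 2, that of sulp-4 also without each of the other 3 libraries. Of these markers 7 rose and 0 fell with library size only. Of 32 somatic gonad, vulva and uterus genes 10 fell, including gon-4 (−0.79) and lin-3 (−0.73), and egl-43 (0.94), nhr-67 (1.72), nhr-6 (1.14), fos-1 (0.36) and hlh-8 (0.61) rose (the same adjusted over the list alone). That list did not pass camera (adjusted p = 0.545), whose direction was down while the median was 0.09, and 3 members rose without OP50 replicate 1, 2 or 3 or FUDR replicate 2, where fos-1 (adjusted p up to 0.0679) and hlh-8 (up to 0.136) were not called. The counts were 10 up and 8 down with library size only, with a median of 0.31.

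**Figure D3:**
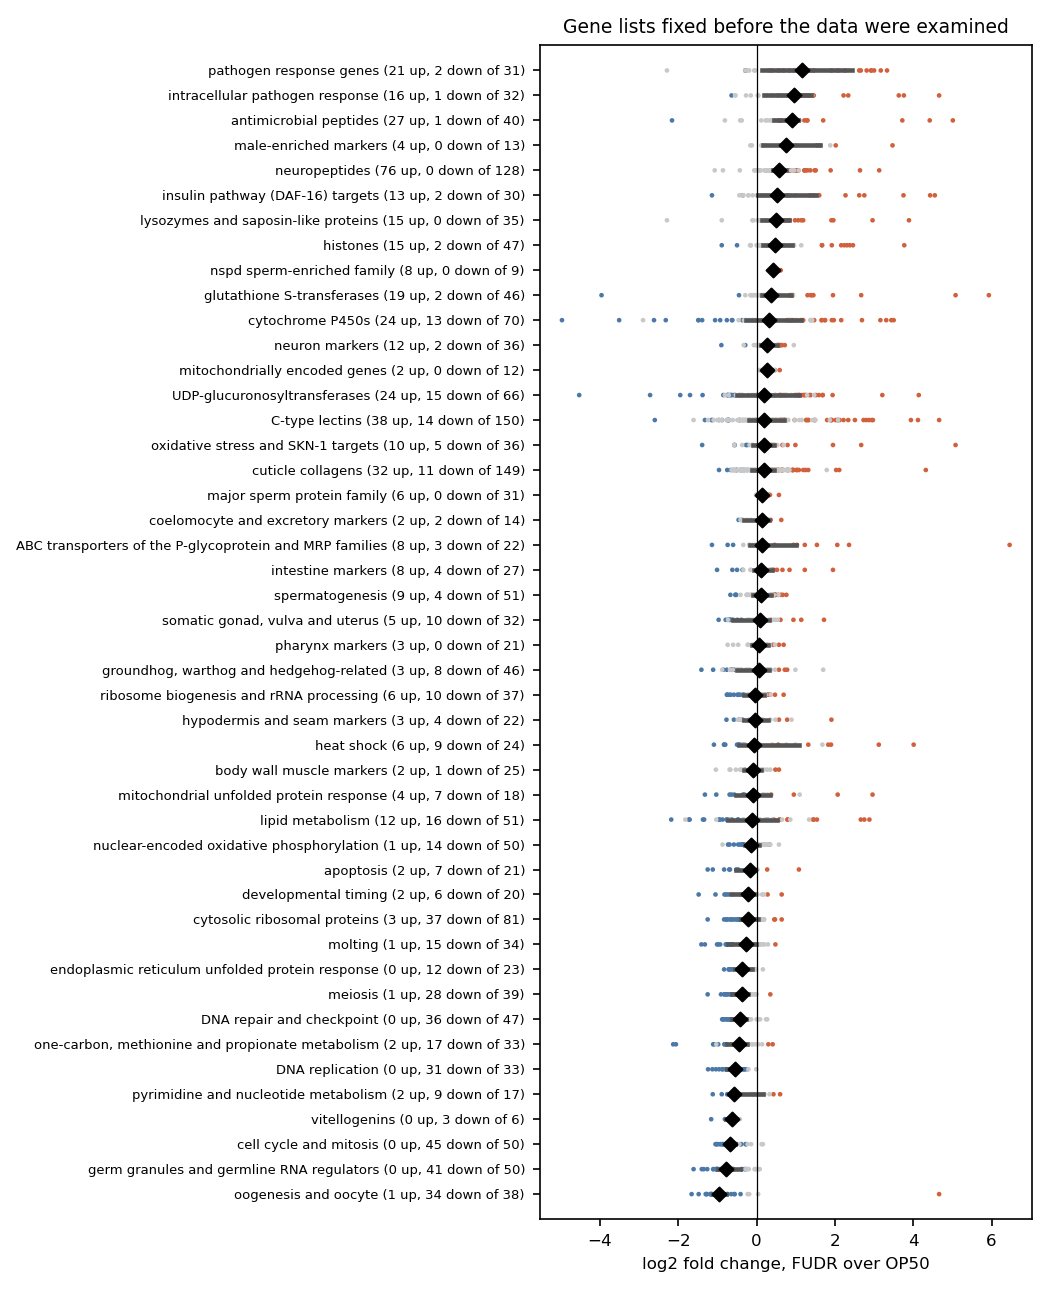
Log2 fold change of FUDR over OP50 for each tested member of the 46 lists, with called members in orange (higher) or blue (lower), a diamond at the list median and a bar from the lower to the upper quartile. The oogenesis list has the lowest median (−0.97) and the pathogen response list the highest (1.17). With library size only in place of TMM, the medians of the apoptosis, timing, heat shock, muscle, hypodermis, lipid, mitochondrial stress, oxidative phosphorylation, ribosomal protein and ribosome biogenesis lists change from negative to positive.

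Across the 46 lists, 29 passed camera (14 up and 15 down), 28 passed fry and 0 passed with an estimated correlation. Splits of the 6 libraries that mix the groups also passed between 11 and 24 lists by camera and called 0 genes. Such splits keep part of the difference between treatments, so they do not measure false calls. Statements here rest on the counts of single genes. Among 151 families of gene symbols 60 passed camera (30 up and 30 down) and 0 with an estimated correlation. The transthyretin-related ttr family rose in 38 of 57 members, including ttr-33 (1.18) and ttr-26 (1.24), and fell in ttr-50 (−0.79). The F-box family fbxa rose in 56 of 127 members, including fbxa-163 and fbxa-108 (1.66), and fell in fbxa-215 (−0.77), fbxa-206 (−0.51), fbxa-170 (−0.67), fbxa-216 (−0.70) and fbxa-153 (−0.90). The secretory pathway sec family fell in 15 of 19 members, including sec-61.B (−1.09) and sec-61.A (−1.32), and rose in sec-11 (0.49). The vacuolar ATPase family vha fell in 13 of 20 members, including vha-12 (−0.82) and vha-18 (−0.60), and rose in 0. Of the tested nuclear hormone receptor genes (nhr) 75 rose and 17 fell, with nhr-42 at 1.25 and nhr-114 at −2.06. The camera adjusted p was 5.31e-07 for ttr, 2.29e-06 for fbxa, 4.23e-05 for sec, 4.73e-05 for vha and 0.00107 for nhr, and with an estimated correlation the adjusted p was 0.499 for ttr and vha and 0.496 for the others. With library size only, 3 fbxa genes, 9 vha genes and 6 nhr genes fell, and 71 fbxa genes rose. The fbxa-153 call was lost without FUDR replicate 2 (−0.78, adjusted p = 0.0579).

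Changed genes were unevenly spread over chromosomes. On chromosome V 883 of 3515 tested genes rose and 554 fell, and on chromosome I 441 of 2680 rose and 728 fell. Genes on X fell in 15.4% of cases against 22% on autosomes, an odds ratio of 0.645 (95% interval 0.572 to 0.725, two-sided Fisher's exact p = 2.89e-14, over genes, which are not independent). Genes on X rose in 18.5% of cases against 20.2% on autosomes, an odds ratio of 0.896 (0.8 to 1, exact p = 0.0514), which passed the threshold with library size only (0.908, exact p = 0.0396) and without any single library (exact p between 0.000269 and 0.0433) other than OP50 replicate 3 (0.926, exact p = 0.232), and which was 1.02 with the 5 CPM filter. By biotype, 27 of 78 lincRNA genes rose, and 44 of 128 ncRNA genes rose and 9 fell.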

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

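The tests in this part were chosen after the results were seen. Reads assigned to no gene made up 0.448% ± 0.0199 of all counts in the FUDR libraries and 0.324% ± 0.0106 in the OP50 libraries (SD, n = 3 each). Genes with too few counts to be tested held 0.0235% ± 0.00172 of gene counts in FUDR and 0.0142% ± 0.0013 in OP50. These signals lie outside the counts that were compared, are above the level of the OP50 controls and did not overlap between groups, which for 3 against 3 libraries gives an exact permutation p of 0.1, the smallest possible.

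The gain in untested genes and outside genes bears on the finding that 1348 genes rose at least 2-fold while 310 fell. An even background of reads, as from genomic DNA, was tested by the gain in CPM per kb of exon. The background gained at most 0.0102 CPM per kb, and 99.4% of the genes that rose at least 2-fold gained over 10 times what this gives for their length, so it is too small to be their source. After thinning of all libraries to the shallowest, 1301 genes still rose at least 2-fold, which argues against a difference in depth. Less germline RNA, raising the RNA of all other tissues alike, would move neuropeptide and body wall muscle genes together. The difference, neuropeptides minus muscle, was 0.76 higher in FUDR (log2, pooled SD 0.28). It was already −6.58 in OP50, and median log2 fold changes of all genes ran from 0.44 under 1 CPM to −0.31 over 100 CPM. The contrast therefore cannot tell a difference between tissues from one of expression level. The neuropeptide list shares nlp genes with the antimicrobial peptide list. Medians of tissue markers lay closer together, at 0.26 for neurons, 0.11 for intestine, 0.06 for pharynx, −0.04 for hypodermis and −0.09 for muscle. Less germline RNA as a source, in whole or in part, is therefore not excluded. A response of somatic cells to FUDR stays open as an explanation and was not tested.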

How the results depend on the processing

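Thinning and the fit of protein-coding genes alone were chosen after the data were seen. The number of changed genes was 6979, between 5402 and 7745 over 11 other choices of test, scaling, filter, block and gene set, and between 5006 and 7234 with 1 library left out. Genes shared with the reported set kept their sign under each of these. Against a 1.5-fold change 1241 were called, 70.43% of them higher, since that test asks for more than any change. The share that rose was 75.07% with library size only. The replicate numbers did not clearly pair the libraries (correlations of residuals 0.055, −0.017 and 0.058). The second principal component (10.5% of the variance) did run in replicate order in both groups, at 26.2, −10.9 and −18.8 in OP50 and 24.1, 5.45 and −26.1 in FUDR. A batch by replicate number is therefore not excluded. With the numbers as a block 6762 genes were called and the mitochondrially encoded list passed (adjusted p = 0.0325). There vit-3 (0.0638) and vit-4 (0.0673) were not called, and ttn-1 (0.0144) and WBGene00010963 (0.026) were called.

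With an estimated correlation 0 lists and 0 families passed, against 29 and 60. The estimate was 0.0085 for the intracellular pathogen response list and 0.00128 for C-type lectins, under the preset 0.01. Both lists were lost all the same, so correlation between genes is not the only source of the loss. The few degrees of freedom left by the libraries also enter that test. Fry, which does not compare a set with other genes, passed 97 families. The 5 CPM filter passed 33 families, with fewer genes and families tested. Lists that passed numbered between 23 and 30 under the other settings and families between 42 and 65. The odds ratio of X for genes that rose was 0.896, and 0.908 with library size only (exact p = 0.0396), 0.868 with the block (exact p = 0.0147), 1.02 with the 5 CPM filter and between 0.812 and 0.926 with 1 library left out, and the cause was not tested. That for genes that fell stayed between 0.58 and 0.742.

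The camera direction of lists that did not pass reversed in 6 cases, with medians of 0.08 for cytochrome P450s, 0.08 for ribosome biogenesis and 0.01 for muscle with the 5 CPM filter, −0.13 for pharynx without FUDR replicate 1 (range −0.13 to 0.24), and without OP50 replicate 1 0.12 for hypodermis (range −0.09 to 0.12) and 0.13 for coelomocytes (range 0.09 to 0.19), and the cause was not tested. Of the named genes, 26 lost their call with library size only, 14 with the 5 CPM filter, 3 with DESeq2, 12 with the block, 140 against a 1.5-fold change and between 10 and 38 with 1 library left out. The difference in mitochondrial share stayed positive, between 0.218 and 0.465. Uneven depth did not account for the count, with 6829 called after thinning to the shallowest library, and lower depths were not tried.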

Other observations

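The tests in this part were chosen after the results were seen, except that of a single aberrant library. Of 210 tested members of the DNA replication, cell cycle, meiosis, germ granule and oogenesis lists 179 fell, which may come from several sources. The replication and cell cycle lists also cover divisions of somatic cells. A smaller germ line lowering all germline RNA alike would lower sperm and oocyte genes together, but the spermatogenesis list rose against the oogenesis list by 0.87 (log2, pooled SD 0.15). The difference between these lists was already −4.39 in OP50. Median log2 fold changes of all genes ran from 0.29 at 1 to 5 CPM to −0.31 over 100 CPM. Part of the 0.87 therefore cannot be told apart from expression level. The contrast covers an even loss only, and a germ line reduced in parts other than sperm stays open. The choice among these scalings is argued against as the whole source, since without a scaling factor the median of all 210 members was −0.45 (quartiles −0.66 and −0.19, against a median of −0.68 with TMM), with 148 lower and 6 higher. The amount of RNA per worm was not measured. Younger FUDR worms cannot be told apart, because 3 of 4 adult collagens were called higher (col-7, col-19 and col-62, but not col-63, at −0.25) while 3 of 6 vitellogenins were called lower, a count that was 1 with library size only. Without FUDR replicate 3 the calls of col-7 (adjusted p = 0.136) and col-62 (0.0775) were lost. An effect of FUDR on oogenesis, or on the timing of the switch from sperm to oocytes, stays open and was not tested.

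The methionine, folate and propionate list fell in 17 of 33 tested members, a share near that of all genes over 100 CPM (970 of 1931). A smaller share of intestinal RNA would lower intestine markers alike, but the list fell against the intestine list by 0.67 (a difference of −0.67 on the log2 scale, pooled SD 0.13). That contrast covers an even loss only, since intestine markers changed in both directions, with 8 of 27 higher and 4 lower. A smaller intestinal share masked by markers that rose is not excluded. A single aberrant library is argued against for the 17 members called, since at least 12 of them were still called lower whichever library was left out. Members not called with all 6 libraries lie outside that test. Over the whole list between 12 and 19 members were lower with 1 library left out. An effect of FUDR on the worms' own metabolism, or through their bacteria, could underlie it and was not tested. Less germline RNA was not tested as a source of this fall either. Some members of this list were uneven among the OP50 libraries. The propionate pathway gene hphd-1 had 73.05, 195.21 and 267.43 CPM in OP50 and 50.63, 39.24 and 32.62 CPM in FUDR (−2.13, edgeR adjusted p = 0.00658), a call lost without FUDR replicate 1 (0.0632) or 3 (0.12) and without the count filter (0.0622). The acyl-CoA dehydrogenase gene acdh-1 had 12.87, 81.27 and 193.24 CPM in OP50 and was not called (−1.03, adjusted p = 0.357), but was called without OP50 replicate 1 (−1.54, adjusted p = 0.0138), and ech-6 behaved alike (−0.43, adjusted p = 0.244, and −0.72, adjusted p = 0.00792, without OP50 replicate 1).

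Of the 10 ways to split the 6 libraries into groups of 3, the real one called 6979 genes and the highest other 0 (1 split with a count as large, the real one). For lists the real split passed 29 and the highest other 24, and for families 60 and 45 (again 1 split each). There are too few splits for a share under 0.05. Each mixed split keeps part of the difference between treatments and puts the rest into the spread within its groups. The lists passed and the 0 genes called there therefore do not measure false calls. Camera with its preset correlation was not taken by itself to set the real groups apart.

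Some genes outside the naming rule were picked after their values were seen. The gene F08G2.5 (chromosome II, 13833095 to 13833631) went from 1.55 ± 0.491 to 412 CPM on average (8.04, edgeR adjusted p = 9.95e-06), and C25F9.11 (chromosome V) from 0.22 ± 0.137 to 31.3 CPM on average (7.05, edgeR adjusted p = 0.000127). The galectin gene lec-8 went from 102 ± 1.95 to 321 ± 15.2 CPM, and the germline Notch receptor gene glp-1 from 190 ± 6.41 to 98.2 ± 18 CPM. Vitellogenin genes held 5.68%, 6.58% and 7.02% of counts in the OP50 libraries and 6.2%, 4.91% and 3.68% in the FUDR libraries, and col-19 had a mean of 2240 CPM in OP50. These are high for genes known mainly from adults, the labels give the L4 stage without a time of collection, and the stage was not tested.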
